A study of Homo sapiens with 6 samples.

How the data were processed

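RNA of doxycycline-treated cells was measured on 6 arrays, 3 for Tet-Axl 1 and 3 for Tet-Axl 2. Per the labels' protocols, total RNA was extracted from cell pellets and 400 ng were amplified and labelled with the dye Cy3. Per the file headers, the arrays were human Agilent 1-colour arrays annotated on hg19 and the images were read with Feature Extraction 10.7.3.1. Each file held 44495 spots, 43118 of them not controls, for 34127 probes. The deposited intensity values of each spot are, per the file headers, a processed signal that the software had corrected for background and spatial trends and replaced by a surrogate value for dim spots, and a mean signal with its local background. The authors' deposited value table is on a log2 scale. How it was made is not given in the sources used here. Its columns had medians from 7.30 to 7.30 and nearly the same quartiles, as after quantile normalization, with no centring of genes, and 5 of 6 correlated best with the log2 mean signal of their own array. The exception, Tet-Axl 2 replicate 3, had r = 0.99419 with its own and 0.99427 with another array. After each spot was centred on its mean over the arrays, a check added after the data were seen, all 6 columns correlated best with their own array (r from 0.653 to 0.918, across spots, which are not independent replicates). Its rows were named through the spot number, and it served only as an alternative.

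The processed signal had a 75th percentile between 471 and 769 per array. Between 20833 and 23488 probes were well above background, 8227 to 9905 spots carried a surrogate value, 297 to 431 spots per array were outliers and left out, and 0 were saturated. The software graded 5 arrays as in range and replicate 1 of Tet-Axl 2 for evaluation. Net signal of the negative controls lay between 21.1 and 32.3, with the 2 highest values on the arrays of the first scan run.

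Log2 processed signal minus the 75th percentile of the array was analysed. Control spots were left out and spots of a probe averaged. A probe was kept if it was well above background on all 3 arrays of at least 1 line, and the brightest kept probe by mean over the 6 arrays stood for its gene. Where a called gene had more than 1 kept probe (222 genes), 13 had a probe of the opposite sign, and in 0 did that probe pass the threshold. Probes were named through a RefSeq gene table (GRCh38.p14, used for names only). Of them 25422 matched by accession and 1545 by symbol or synonym, and 7160 matched nothing and kept the name given by the array, so that 16969 features were tested, 13956 with a matched symbol. Coordinates are those of the array's hg19 annotation.

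The lines were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). A gene with no probe well above background on any array of 1 line has a bound there, the mean log2 level of the bright line against the mean of, per array, the higher of the lowest level among probes well above background and that of the dim probe. There were 59 called genes of this kind higher and 30 lower in Tet-Axl 2. A dim probe can lie above the lowest level among probes well above background. IFIT1 did so on Tet-Axl 1 replicate 2 (−5.60 against −5.74). Folds given with the words at least are therefore approximate bounds and not strict minima. Gene lists were tested with camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over 34 lists with at least 5 measured genes), with camera at an estimated correlation, and with fry, which asks whether the genes of a list move one way without comparing them with other genes (adjusted p = 0.0010 for interferon-stimulated and 0.0014 for immediate early genes). Fry also passed lists that camera did not call. These were WNT targets (fry adjusted p = 0.0041), TGF-beta response genes (0.027), growth arrest genes and basal markers (0.045 each), and androgen receptor and YAP targets (0.049 each). Of the 10 lists that camera called at the preset correlation, antigen presentation genes (0.055) and metallothioneins (0.13) missed with fry, and 0 were called by camera with an estimated correlation. The form with an estimated correlation takes its degrees of freedom from the few arrays. A miss there is therefore weak evidence that a list does not differ. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.

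Before the data were examined, 36 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The rule took the AXL family, the 10 highest and 10 lowest called genes that were well above background on all 6 arrays with lines that did not overlap, the 5 largest bounds each way, and up to 2 called members each way of each list described. Further members of small counts, IFNA4, IFNL2 and a stretch of chromosome 8 were chosen after their values were seen. Of 874 list genes, 860 were on the array. CD24, whose probe was annotated to another copy of the gene, is not described, and some other list members are not reported here.

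Titles number the replicates 1 to 3 in each line. The deviations of same-numbered arrays from their line means correlated across genes at 0.70, 0.61 and 0.64, so the numbers were taken to pair the arrays. This pairing comes from the values and not from a label that states a shared day or batch. Slides were told apart through the file headers. Replicate 1 of both lines lay on 1 slide and in the first scan run. Replicates 2 and 3 lay on 1 slide per line, in the second scan run. Slide and scan run were tested as blocks.

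The procedure was tested on simulated data built from the real means and spreads of 16964 features, with 200 genes changed in each of 20 runs. Of genes changed by 0.5 on the log2 scale, 6.0% were recovered, against 59.8% at 1, 90.1% at 2 and 97.9% at 4. Unchanged features made up 5.65% of the calls. A list of 30 genes shifted by 0.5 passed in all 20 runs. The simulated genes varied independently, which real genes do not.

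Alternatives were quantile and median scaling, normexp background correction (offset 50) with quantile normalization, the value table, filters on dim probes, other ways to join the probes of a gene, array weights, a trended robust spread, slide, scan run and replicate blocks, and leaving out each array. A fit to replicates 2 and 3 alone and the replicate block with an estimated correlation were added after seeing the data.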

Results

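Gene expression was measured in C4-2B cells (C42B in the labels), a human prostate cancer cell line, in 2 Tetracycline-On lines that the labels call Tet-Axl 1 and Tet-Axl 2. AXL is a receptor tyrosine kinase, and in Tet-On cells doxycycline switches on an introduced construct, which the labels describe no further than by these names. Both were starved overnight in 0.1% serum, seeded at 300000 cells per plate and kept for 4 days with doxycycline at 100 ng/mL. The submitters' descriptions also call the lines "Low agg" and "High agg" and do not spell the word out. Each line was profiled on 3 one-colour arrays, and no array without doxycycline was part of the data, so the only comparison was line against line. The series title names AXL as a putative tumour suppressor and dormancy regulator, and the comparison asks how the transcriptomes of these lines differ under doxycycline. Differences are given as Tet-Axl 2 minus Tet-Axl 1 on the log2 scale with their standard error (SE) and n = 3 arrays per line. Between 61.0% and 68.8% of the probes were well above background on an array, and the small number of arrays limits the precision. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical.

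Tet-Axl 2 cells had higher levels of interferon-stimulated genes such as IFI27 (42.5-fold) and of immediate early genes such as EGR1 (8.93-fold), and lower levels of the growth factor gene BMP7 (63.7-fold) and the lipase gene LPL (21.8-fold). The fold of IFI27 is uncertain, because on Tet-Axl 1 replicate 1 it lay near the lowest level of probes well above background. As sets, the interferon-stimulated and the immediate early genes passed with a preset correlation between genes, with 27 of 34 and 12 of 23 members higher, and missed with an estimated one (adjusted p = 0.14 for each). With so few arrays, a miss with an estimated correlation is weak evidence that a list does not differ. Of 16969 features tested, 671 were higher and 612 lower in Tet-Axl 2. For AXL itself no difference passed the test. The array carries a single AXL probe, A_23_P208389, at chromosome 19, 41767395 to 41767454 on the plus strand (hg19), which starts at base 4460 of the transcript the array names. It was well above background on all 6 arrays and differed by 0.11 ± 0.21 (SE, n = 3, limma adjusted p = 0.80), with a 95% confidence interval from −0.39 to 0.62. Replicate 1 of each line shared a slide, and there the difference was 0.09. The 2 arrays of each line in the second scan run differed by 0.12. The direction turned to −0.04 without Tet-Axl 1 replicate 1 and to −0.07 without Tet-Axl 2 replicate 3. Whether the construct holds the sequence of this probe is not given in the sources used here, and so its level does not check how strongly the construct was induced.

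Among the ligands of AXL and its relatives, the transcripts of the vitamin K-dependent proteins GAS6 and PROS1 went opposite ways. GAS6 was lower in Tet-Axl 2 by −0.92 ± 0.17 (limma adjusted p = 0.022), and PROS1 was higher by 0.91 ± 0.12 (adjusted p = 0.0049). On the shared slide GAS6 differed by −0.52, against −0.86 and −1.38 in the other same-numbered pairs. For PROS1 these differences were 0.78, 1.00 and 0.95. On Tet-Axl 1 replicate 1, PROS1 (−4.65) lay near the lowest level of probes well above background (−4.82), so the size of its difference is uncertain. The related receptors TYRO3 (0.09 ± 0.10) and MERTK (−0.01 ± 0.21) and the lectin LGALS3 (−0.11 ± 0.12) did not pass the threshold, and TULP1 was too dim to test. The MERTK difference was positive under each of the other scalings, from 0.07 to 0.12, and that of LGALS3 was 0.01 with the median in place of the 75th percentile. Of the 6 measured members of this list, 1 was higher and 1 lower, with the same counts adjusted over the list alone, and the list as a set did not pass (median 0.04, 0.07 to 0.17 under the other scalings, camera adjusted p = 0.73).

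**Figure D1:**
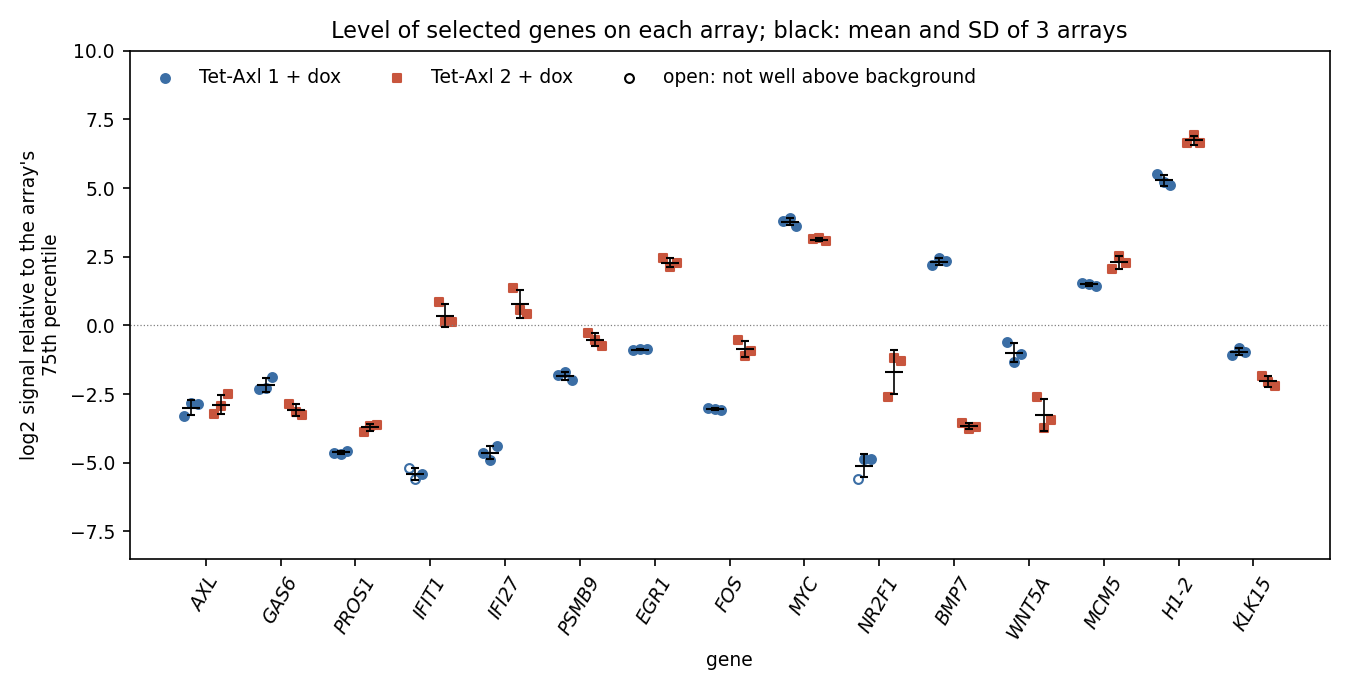
Log2 signal relative to the 75th percentile of the array (vertical axis) for 15 named genes (horizontal axis), 1 point per array, circles for Tet-Axl 1 and squares for Tet-Axl 2, with the mean and SD of 3 arrays in black and open points where the probe was not well above background. The lines overlap for AXL, while BMP7 is lower in Tet-Axl 2 by −5.99 and EGR1 higher by 3.16.

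Interferon-stimulated genes formed the largest group that was higher in Tet-Axl 2. Of 34 measured members, 27 were higher, 0 were lower and 7 did not pass the test (31 higher adjusted over the list alone), and the list as a set was higher (camera adjusted p = 2.7e-35, but adjusted p = 0.14 with an estimated correlation). IFI27 rose by 5.41 ± 0.26 (42.5-fold, limma adjusted p = 9.0e-05) and IFITM1, which restricts virus entry, by 4.26 ± 0.31. On Tet-Axl 1 replicate 1, IFI27 (−4.63) lay near the lowest level of probes well above background (−4.82), so its fold is uncertain. IFIT1, an RNA-binding antiviral protein, differed by 5.76 ± 0.23 but was well above background on only 1 of the 3 Tet-Axl 1 arrays. IFIT2 and IFIT3 were not well above background on any Tet-Axl 1 array. By approximate bounds they were at least 43.2-fold and at least 26.3-fold higher in Tet-Axl 2. The median of the list was 1.80 (1.17 to 1.93 under the other scalings), or 1.54 with such genes at their bound, and it was 2.15 on the slide that held both lines, against 1.44 and 1.63 in the other same-numbered pairs. Probes of the IFIT and IFITM families can bind close relatives, so the split between members of a family is uncertain.

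Antigen presentation genes were higher as a set (camera adjusted p = 1.2e-04, but adjusted p = 0.59 with an estimated correlation), with 4 of 18 members higher, 0 lower and 14 not past the test (6 higher adjusted over the list alone). TAP1 and ERAP1 were among the 4. PSMB9, a subunit of the immunoproteasome, rose by 1.32 ± 0.16 and NLRC5, an activator of MHC class I genes, by 1.09 ± 0.18. Their list median was 0.31, and 0.50 on the shared slide. In the NF-kB and cytokine list, 3 of 13 members were higher and 0 lower (6 higher adjusted over the list alone and with the replicate block), namely BIRC3, an apoptosis inhibitor, at 2.12 ± 0.19, TNF at 1.27 ± 0.21, and IL32. BIRC3 was well above background on 2 of the 3 Tet-Axl 1 arrays. On Tet-Axl 1 replicate 1, TNF (−4.52) lay near the lowest level of probes well above background (−4.82). That list passed with camera at adjusted p = 0.025, with a median of 0.10 (0.04 to 0.23 under the other scalings) and 0.09 on the shared slide, and missed with an estimated correlation (adjusted p = 0.59). It also missed without Tet-Axl 2 replicate 1 (adjusted p = 0.089) and in replicates 2 and 3 alone (adjusted p = 0.077), and its median was −0.07 with no filter on dim probes, while adjusted p ranged from 0.0093 to 0.11 over the alternatives with a preset correlation.

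Immediate early genes, which respond within minutes to growth factor signals, were higher in Tet-Axl 2 as a set (camera adjusted p = 1.0e-09, and adjusted p = 0.14 with an estimated correlation). Of 23 measured members, 12 were higher, 1 was lower and 10 did not pass (17 higher and 2 lower adjusted over the list alone). The transcription factors EGR1 and FOS rose by 3.16 ± 0.12 and 2.19 ± 0.16 (limma adjusted p = 4.7e-05 and 0.00046), while MYC fell by 0.65 ± 0.11 on the log2 scale (adjusted p = 0.018). The list median was 0.76, and 0.96 on the shared slide.

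The lists of G1/S and histone genes were also higher as sets with a preset correlation and missed with an estimated one (adjusted p = 0.59 for each). In the G1/S list 5 of 30 genes were higher, 0 were lower and 25 did not pass over all genes tested, against 20 higher adjusted over the list alone and 20 with the replicate number as a block. Those 5 were GINS2, CHAF1B, MCM10, CDT1 and MCM5. CDT1, which licenses replication origins, rose by 0.82 ± 0.14 and MCM5, a subunit of the replicative helicase, by 0.80 ± 0.14. All 30 differences were positive, with a median of 0.51, and 0.28 on the shared slide (camera adjusted p = 2.0e-12). Replication-dependent histone genes had 7 of 14 members higher and 0 lower (11 adjusted over the list alone, 12 with the replicate block), among them H1-2 at 1.46 ± 0.15 and H2AC8 at 0.85 ± 0.15. Their median was 0.68, and 0.27 on the shared slide (camera adjusted p = 3.7e-08). Histone genes are near-identical copies and their probes may not tell members apart. The G2/M list, which marks cells in mitosis, had 0 of 31 genes past the limma test, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05. Its median was 0.13 (0.09 to 0.26 under the other scalings) and −0.07 on the shared slide (camera adjusted p = 0.090), and the list passed in replicates 2 and 3 alone with the preset correlation (adjusted p = 0.0034), while over all arrays it had adjusted p = 0.91 with an estimated correlation.

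Genes linked to growth arrest and dormancy went both ways and did not pass as a set with camera (median −0.03, −0.01 to 0.10 under the other scalings and 0.02 on the shared slide, while camera, at adjusted p = 0.97, pointed up). With fry the list passed narrowly (adjusted p = 0.045). Of 31 measured, 3 were higher, 4 lower and 24 did not pass (4 and 5 adjusted over the list alone). BMP7, a secreted growth factor, showed the largest decrease among genes measured on all 6 arrays, −5.99 ± 0.12 (63.7-fold lower, limma adjusted p = 7.1e-06), and the secreted ligand WNT5A fell by 2.26 ± 0.31 on the log2 scale. The nuclear receptor NR2F1 rose by 3.42 ± 0.41 and was well above background on 2 of the 3 Tet-Axl 1 arrays, and GADD45B rose by 1.24 ± 0.17. CDKN2B, well above background on 1 of the 3 Tet-Axl 1 arrays, was also higher, and GADD45A and GAS5 lower. In the TGF-beta response list, 2 of 18 genes were higher and 2 lower (3 and 5 adjusted over the list alone, 4 and 5 with the replicate block, camera adjusted p = 0.91), with a median of −0.01 that was 0.01 to 0.11 under the other scalings and 0.10 on the shared slide. INHBA, a subunit of activin, was not well above background on any Tet-Axl 2 array and, by an approximate bound, was at least 10.04-fold lower there. PMEPA1 fell by 1.02 ± 0.16 on the log2 scale, while ID1 rose by 1.81 ± 0.32 and JUNB by 0.92 ± 0.20.

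**Figure D2:**
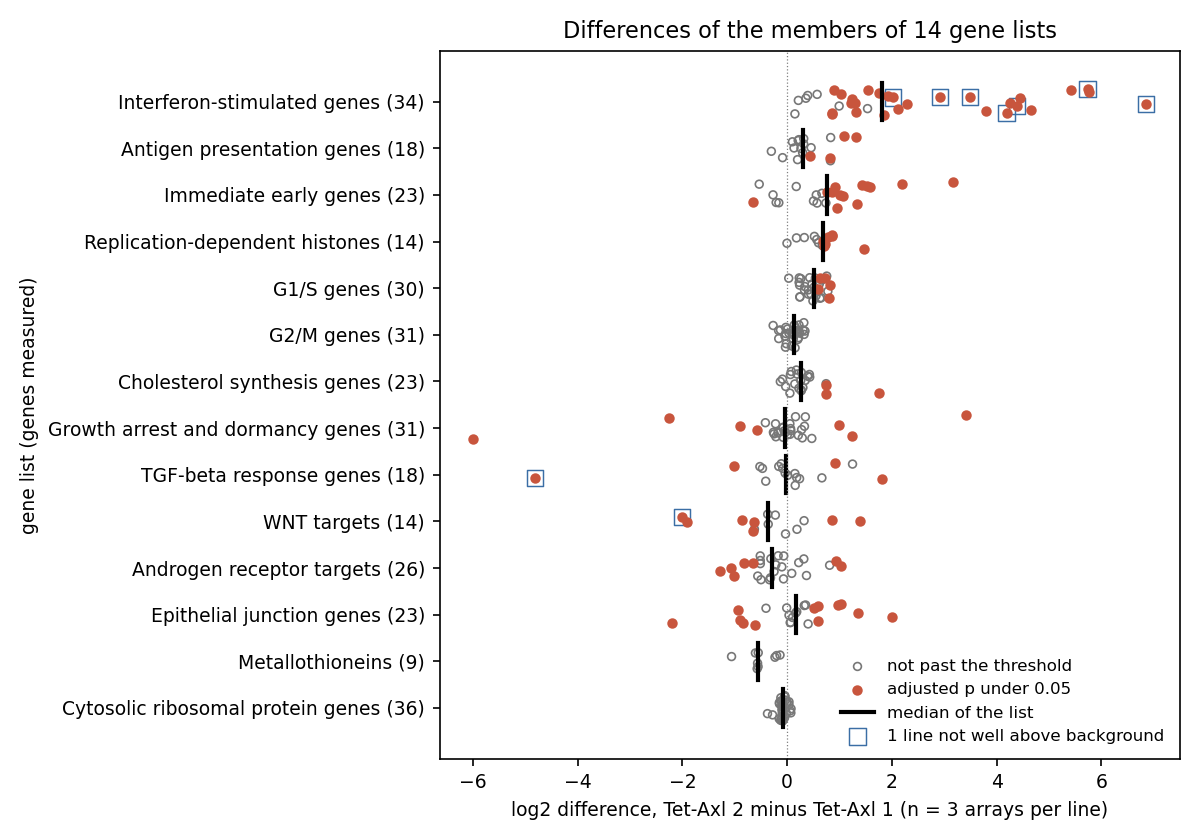
Log2 difference, Tet-Axl 2 minus Tet-Axl 1 (horizontal axis), of each measured member of 14 gene lists (vertical axis, genes measured in brackets), filled where the adjusted p was under 0.05, with the list median as a bar and a square around members that were not well above background in 1 line, whose plotted difference is a fitted value and not a bound. The interferon-stimulated genes have a median of 1.80 and the immediate early genes of 0.76, while the cytosolic ribosomal protein genes lie close together around −0.08, a median that is 0.05 with the median in place of the 75th percentile.

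Epithelial junction genes changed in both directions, with 7 of 23 higher and 5 lower (8 and 5 adjusted over the list alone, median 0.16, 0.07 to 0.29 under the other scalings, camera adjusted p = 0.086). The tight junction proteins OCLN and CLDN4 rose by 2.00 ± 0.14 and 1.35 ± 0.19, while the desmosome proteins PKP2 and DSC2 fell by 2.20 ± 0.19 and 0.94 ± 0.15 on the log2 scale, and DSG2, CDH3 and GRHL2 were also lower. Among androgen receptor targets 2 of 26 were higher and 5 lower (3 and 8 adjusted over the list alone, 3 and 10 with the replicate block), with a median of −0.28 (−0.29 to −0.15 under the other scalings) and a camera adjusted p of 0.074, or 0.047 in replicates 2 and 3 alone, and over all arrays adjusted p = 0.59 with an estimated correlation. Their median was −0.11 on the shared slide, against −0.38 and −0.29 in the other same-numbered pairs. TRPM8, an ion channel, fell by 1.29 ± 0.30 and the kallikrein KLK15 by 1.08 ± 0.14 on the log2 scale, while ALDH1A3 rose by 0.93 ± 0.17. PMEPA1, KLK2 and STEAP2 were also lower. STEAP4 rose by 1.03 ± 0.19 and was well above background on 2 of the 3 Tet-Axl 1 arrays. WNT targets had 2 of 14 members higher and 5 lower (2 and 6 adjusted over the list alone) and a median of −0.37 (−0.32 to −0.24 under the other scalings, camera adjusted p = 0.091). The median of the WNT targets was −0.15 on the shared slide, against −0.55 and −0.45 in the other same-numbered pairs. SP5 was, by an approximate bound, at least 2.12-fold lower and TNFRSF19 higher by 1.38 ± 0.19. AXIN2, FZD7, MYC and APCDD1 (well above background on 1 of the 3 Tet-Axl 2 arrays) were lower and TCF7L2 higher.

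Further genes with large differences fell outside these groups. Among genes well above background on all 6 arrays, TMEFF2, a transmembrane protein of prostate epithelium, was 17.3-fold higher in Tet-Axl 2. The secreted protease KLK6 was 16.1-fold higher, SFN (14-3-3 sigma) 14.9-fold, SIPA1L2 9.97-fold, AGR2 9.62-fold and TRIM49D2 8.80-fold, and the lipase LIPH rose by 3.42 ± 0.19. The lipoprotein lipase LPL was 21.8-fold lower, GALNT14 9.16-fold, the peroxisomal oxidase ACOX2 8.81-fold, GUCA2B 7.68-fold, the protease HTRA1 7.18-fold, the BMP antagonist GREM1 6.57-fold, the urea cycle enzyme CPS1 5.77-fold, CYP4F8 5.75-fold and ALDH1L2 5.61-fold. The limma adjusted p of these genes lay at or below that of GREM1, 0.023. On Tet-Axl 2 replicate 1, GUCA2B (−4.52) and ALDH1L2 (−4.55) lay near the lowest level of probes well above background (−4.71), so their folds are uncertain. TRIM49D2, CYP4F8 and KLK6 belong to families of similar genes, so cross-hybridisation is possible. Several genes were well above background in a single line, and their folds are approximate bounds. In Tet-Axl 2, the ephrin receptor EPHA6 was at least 11.9-fold, TRPS1 at least 9.85-fold and the cadherin CDH18 at least 9.11-fold higher. In Tet-Axl 1, the protease MMP26 was at least 27.5-fold, FRAS1 at least 24.3-fold, the synaptic protein ERC2 at least 18.8-fold and the pseudokinase TRIB2 at least 9.27-fold higher.

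Over all features, 1283 passed an adjusted p of 0.05 in limma, and 580 of these were at least 2-fold apart (334 higher, 246 lower). In 29.4% of all features the lines did not overlap, against 10% by chance for exchangeable arrays, a value that leaves out the pairing of the arrays by number. The median difference of all features was −0.04, and 0.08 when each array was scaled to its median, which gave 724 higher and 373 lower in place of 671 and 612. With the replicate number as a block the count was 3667 (1598 higher, 2069 lower). The count fell to 722 without Tet-Axl 1 replicate 1, to 771 without its replicate 3, to 575 without Tet-Axl 2 replicate 2 and to 541 without its replicate 3. Slide and line overlapped in part. With the slide as a fixed block, where the shared slide alone gives the difference, 206 were called, with the slide as a random block 1127, with the scan run as a block 1926, and within the second scan run alone 798.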

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

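Of the tests in this part, the fit to replicates 2 and 3 alone and the replicate block with an estimated correlation were chosen after the data were seen. Of 101 called genes named by the rule, 39 stayed past the threshold under every alternative with a test, 0 turned their direction, and leaving out 1 array kept between 70 (without Tet-Axl 2 replicate 3) and 93 (without Tet-Axl 2 replicate 1). The lines overlapped in 0 called features, so leaving out an array or adding a fixed block could not turn a direction. The fewest kept under a single alternative were 41, with the slide as a fixed block, where 1 array per line gives the difference. Against 1283 called, the count was 525 with no filter on dim probes (468 of the 1283 among them), 3922 with array weights (1282 shared), 206 with the slide as a fixed block (192 shared), 1926 with the scan run as a block (1283 shared), 798 in replicates 2 and 3 alone (680 shared), and between 541 and 1410 when 1 array was left out. Against 580 at least 2-fold apart, 274 were counted with normexp and quantile normalization, 267 with the value table, 383 when a probe had to be well above background on all 6 arrays, and 206 with the slide as a fixed block, and leaving out 1 array gave 457 to 673. The smaller counts under the filter on all 6 arrays and in replicates 2 and 3 alone follow in part from fewer features or arrays. For the others the cause was not tested.

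The replicate block raised the count of called features from 1283 to 3667, with all 1283 among them, and kept all 101 named calls and all 10 list calls. Apart from the counts within lists, it changed no other call, except that the hypoxia and glycolysis list passed (adjusted p = 0.045, and adjusted p = 0.89 with an estimated correlation). With an estimated correlation 0 lists were called, and 0 with the replicate block and an estimated correlation. The block leaves still fewer degrees of freedom, and with it even the interferon-stimulated list had camera adjusted p = 0.80. These counts of 0 therefore cannot tell whether a list differed. With 1 array left out, between 8 and 13 lists were called.

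The AXL difference ranged from −0.075 to 0.27 when 1 array was left out and reached 0.43 over all alternatives. It did not pass the threshold under any alternative (limma adjusted p from 0.15 to 0.97). It turned negative without Tet-Axl 1 replicate 1 (−0.04) and without Tet-Axl 2 replicate 3 (−0.075). LGALS3, not called, turned positive with the median in place of the 75th percentile (0.014) and with the slide as a fixed block (0.036). MERTK, not called, turned positive with quantile normalization (0.12), the median (0.12), normexp (0.085), the value table (0.073), the slide as a fixed (0.35) or random block (0.030), and ranged from −0.24 to 0.11 when 1 array was left out. The cause was not tested.

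Interferon-stimulated, immediate early, G1/S, histone, cholesterol synthesis and antigen presentation lists passed under all 21 alternatives with a preset correlation. The NF-kB, cancer-testis and metallothionein lists passed under 16 of 21 and the apoptosis list under 17. The difference between the arrays of the shared slide was tested only with the slide as a fixed block, on the spread of the other arrays. Signal over background limits the dim genes, for which only an approximate bound can be given.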

Other observations

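In this part, the tests of slide, scaling and interferon genes, of array position on the slide, of the chromosome 8 stretch and of replicates 2 and 3 alone were chosen after the result was seen. Cholesterol synthesis genes were higher in Tet-Axl 2 as a set (camera adjusted p = 3.9e-05, and adjusted p = 0.59 with an estimated correlation). Of 23 measured, 3 were higher and 0 lower (4 higher adjusted over the list alone, 8 with the replicate block), with a median of 0.27, and 0.22 on the shared slide. The cholesterol carrier STARD4 rose by 1.75 ± 0.12, HMGCS1, an enzyme of the pathway, by 0.74 ± 0.17, and ACAT2 was also higher. Cancer-testis genes had 2 of 15 members higher and 1 lower (4 and 1 adjusted over the list alone and with the replicate block), with a median of 0.21 (0.14 to 0.34 under the other scalings, camera adjusted p = 0.025, and adjusted p = 0.59 with an estimated correlation). MAGEC2 was at least 7.63-fold (an approximate bound) and MAGEA10 5.04-fold higher, while CTAG2 fell by 1.21 ± 0.15 on the log2 scale. Their families hold close copies. Apoptosis regulators had 4 of 32 higher and 1 lower (5 and 1 adjusted over the list alone, 7 and 1 with the replicate block), with a median of 0.10 (0.08 to 0.23 under the other scalings, camera adjusted p = 0.025, and adjusted p = 0.59 with an estimated correlation). CASP4, BIRC3 and MCL1 were among those higher, and HRK, well above background on 2 of 3 Tet-Axl 2 arrays, was lower by −1.31 ± 0.21. Metallothioneins had 0 of 9 members called by limma over all genes or over the list alone, 1 lower with the replicate block (MT1G) and 2 at an unadjusted p under 0.05. Their median was −0.55, with −1.24 on the shared slide and −0.10 and −0.35 in the other pairs (camera adjusted p = 0.025, and adjusted p = 0.62 with an estimated correlation). Without Tet-Axl 2 replicate 1 the cancer-testis, apoptosis and metallothionein lists were not called (adjusted p = 0.079, 0.064 and 0.089), nor in replicates 2 and 3 alone (0.078, 0.078 and 0.19). The apoptosis list also missed without Tet-Axl 1 replicate 1 (0.051), and the metallothioneins without Tet-Axl 1 replicate 1 (0.071) or replicate 3 (0.059). Over all alternatives with a preset correlation their adjusted p ranged from 0.0083 to 0.095, from 0.0019 to 0.078 and from 2.8e-07 to 0.19.

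Other lists did not pass as sets with camera, and most held genes that moved each way. Luminal markers had 2 of 12 higher and 1 lower (3 and 3 adjusted over the list alone, 4 and 3 with the replicate block), with KRT8 at 0.94 ± 0.14 and DPP4 lower. Their median was −0.09 (−0.14 to 0.04 under the other scalings), while camera pointed up (adjusted p = 0.64). Basal markers had 2 of 8 higher and 1 lower (3 and 2 adjusted over the list alone, median 0.22, 0.08 to 0.35 under the other scalings and 0.47 on the shared slide, adjusted p = 0.25), with LAMB3 at 2.67 ± 0.12, S100A2 higher and ITGA6 lower. Neuroendocrine markers had 1 of 7 higher and 1 lower (2 and 1 adjusted over the list alone, 4 and 1 with the replicate block, median 0.74, 0.30 to 0.86 under the other scalings and 1.10 on the shared slide, adjusted p = 0.12), with DDC at 1.00 ± 0.16 and CALCA at −1.27 ± 0.16. CD68, a lysosomal protein, was higher by 2.96 ± 0.13 and the only one called of 9 leukocyte markers (1 adjusted over the list alone, median 0.05, −0.0015 to 0.18 under the other scalings, adjusted p = 0.64), and CD3D was also called, as lower, with the replicate block. Of 4 fibroblast and osteoblast markers RUNX2 was higher at 1.02 ± 0.17 (1 adjusted over the list alone), and of 4 endothelial markers 0 were called by limma or over the list alone and 1 had an unadjusted p under 0.05, and VWF was called, as higher, with the replicate block. Both lists were too small to test as sets. Mesenchymal transition genes had 1 of 10 higher and 1 lower (2 and 3 adjusted over the list alone, 2 and 2 with the replicate block, median −0.19, −0.13 to −0.07 under the other scalings and 0.08 on the shared slide, adjusted p = 0.64), LOX at 1.06 ± 0.22 and FN1 at −1.14 ± 0.14. Stem cell markers had 3 of 8 higher and 1 lower (the same counts adjusted over the list alone), among them BMI1 higher and LGR4 at −0.86 ± 0.12, with a median of −0.15 (−0.08 to −0.02 under the other scalings) while camera pointed up (adjusted p = 0.62). YAP and TEAD targets had 3 of 15 higher and 1 lower (7 and 4 adjusted over the list alone, 5 and 3 with the replicate block, median 0.19, 0.19 to 0.32 under the other scalings, adjusted p = 0.12). AMOTL2 rose by 1.57 ± 0.15, CCN1 was higher, GADD45A lower, and IGFBP3, well above background on 2 of 3 Tet-Axl 1 arrays, higher by 3.06 ± 0.64. The IGFBP3 difference was 4.70 on the shared slide, against 2.21 and 2.27 in the other same-numbered pairs. Integrins had 0 of 13 higher and 3 lower (0 and 4 adjusted over the list alone, adjusted p = 0.25), ITGB7 at −1.03 ± 0.11, ITGA6 and ITGB2 (well above background on 1 of 3 Tet-Axl 2 arrays), with a median of −0.20 that was −0.08 to 0.02 under the other scalings. Other receptor tyrosine kinases had 3 of 27 higher and 3 lower (4 and 5 adjusted over the list alone, 4 and 6 with the replicate block, median −0.14, −0.08 to −0.01 under the other scalings, mean 0.12, adjusted p = 0.77). EPHA3 (5.58 ± 0.44) and MST1R (2.10 ± 0.24), both well above background on 2 of 3 Tet-Axl 1 arrays, and EPHA2 were higher, and PTK7 (−1.24 ± 0.27), EPHB6 and EPHB2 lower.

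Targets of p53 had 3 of 26 higher and 2 lower (5 and 3 adjusted over the list alone and with the replicate block), with GDF15 at 1.04 ± 0.14, PLK3 and TP53I3 higher, GADD45A lower and SPATA18, well above background on 2 of 3 Tet-Axl 2 arrays, at −1.39 ± 0.24. Their median was −0.05 (−0.04 to 0.08 under the other scalings, and 0.01 on the shared slide), while camera pointed up (adjusted p = 0.74). Hypoxia and glycolysis genes had 1 of 33 higher and 2 lower (the same counts adjusted over the list alone, 5 and 3 with the replicate block), EGLN3 (well above background on 2 of 3 Tet-Axl 1 arrays) higher, CA12 lower by −0.997 ± 0.14, and PDK1 lower. Their median was 0.13 (0.11 to 0.26 under the other scalings, camera adjusted p = 0.064, or 0.045 with the replicate block, which became adjusted p = 0.89 with the block and an estimated correlation). Unfolded protein and amino acid response genes had 1 of 32 higher and 1 lower (1 and 2 adjusted over the list alone, 2 and 4 with the replicate block), ATF3 at 0.76 ± 0.16 and ASNS at −0.58 ± 0.11 (median −0.05, −0.07 to 0.08 under the other scalings, adjusted p = 0.69). Fatty acid synthesis genes had 1 of 19 higher and 1 lower (2 and 2 adjusted over the list alone, 2 and 3 with the replicate block), ELOVL6 at 1.12 ± 0.19 and ELOVL5 at −0.47 ± 0.11 (median −0.08, −0.09 to 0.05 under the other scalings, adjusted p = 0.69). MYC targets had 0 of 32 higher and 1 lower, MYC itself (the same adjusted over the list alone, 2 and 1 with the replicate block, median 0.07, 0.04 to 0.19 under the other scalings, adjusted p = 0.25). By limma, 0 of 33 nuclear respiratory chain genes, 0 of 33 mitochondrial ribosome genes and 0 of 36 cytosolic ribosomal protein genes were called, also adjusted over the list alone, and 3, 1 and 1 had an unadjusted p under 0.05. With the replicate block, 2 respiratory chain genes and 1 ribosomal protein gene were lower. The medians were −0.03, 0.08 and −0.08 (−0.09 to 0.10, 0.04 to 0.21 and −0.05 to 0.05 under the other scalings), with camera adjusted p = 0.64, 0.090 and 0.43.

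The higher level of interferon-stimulated genes was weighed against technical explanations. A slide or scan effect is argued against by the median of 2.15 between the arrays that shared both, and an effect of array scaling by the lowest median under the 4 other scalings, 1.17. The value of 2.15 rests on 1 array per line, and that of Tet-Axl 2, its replicate 1, was graded for evaluation by the software. A candidate explanation is that Tet-Axl 2 cells transcribe an interferon gene, but 0 of the 16 type I and III interferon genes on the array were both well above background in Tet-Axl 2 and called. The condition that would exclude it was reworded after the values were seen: the first wording asked only about detected genes, and IFNA4 (−0.29) and IFNL2 (−0.23), the only 2 well above background, met it, while the later wording requires all 16 to be detected. Because the undetected genes exclude nothing, the explanation stays open, as does a biological difference between the lines, which was not tested.

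The median of the immediate early genes was above 0 in each of the 3 same-numbered pairs, 0.68 in the lowest. The bound set beforehand took this to exclude the handling of a single culture, which holds only if the replicates were separate cultures. The labels do not say so, and this explanation stays open. General cell stress was neither borne out nor excluded by the conditions set beforehand. The 9 measured heat shock genes had a median of 0.21, short of the level set as a sign of stress. By limma 0 were called, and 3 had an unadjusted p under 0.05. Of the 9, 8 had a 95% upper bound below 0.76, the median of the immediate early genes, where exclusion asked for all. General cell stress thus stays open too, as does a biological difference between the lines, which was not tested.

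The variance of the median differences of 10 Mb windows (hg19) was 0.0075, above the 0.0020 to 0.0038 of 1000 shuffles of genes over windows. A copy number difference between the lines would give this result, and is a hypothesis from expression alone. The shuffles treat genes as independent, so they cannot tell it from other reasons for neighbouring genes to differ together. In 0 of 260 windows was the median beyond the largest of any shuffle (0.346). The lowest 2 lay on chromosome 9, at 40 to 50 Mb (−0.278) and 60 to 70 Mb (−0.263). They were uneven over the same-numbered pairs (−0.283, −0.091 and −0.457, and −0.295, −0.088 and −0.481). Whether their probes tell similar sequences apart was not checked. Windows with positive medians included chromosome 4 at 30 to 40 Mb (0.223) and 80 to 90 Mb (0.219), and chromosome 8 at 30 to 40 Mb (0.189) and 70 to 80 Mb (0.220). Another was chromosome 6 at 20 to 30 Mb (0.213), which holds the histone genes H1-2 and H2AC8. Chromosome 8 from 100 to 150 Mb held 201 genes, including MYC, with 80.1% below the median of all genes, a median of −0.21 relative to it (−0.245, −0.235 and −0.229 in the same-numbered pairs), and 26 called lower and 3 higher, whereas the 367 genes from 0 to 100 Mb had a median of 0.06. No technical explanation was tested for this pattern.

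The deviations of same-numbered arrays correlated at 0.60 or more after a smooth trend on probe GC content was taken out and at 0.56 or more after one on signal level, and arrays of different number at the same slide position correlated at −0.32, a value that says nothing about position because deviations from a line mean sum to 0.

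The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For the features called and for those also at least 2-fold apart, 1 of 10 splits, the real one, gave as many. The real split called 1283 features (3860 at an unadjusted p under 0.05) and 580 at least 2-fold apart, and the highest count by limma of any other split was 0 for both (12 to 2676 at an unadjusted p under 0.05). The others among the 4 splits that part all 3 same-numbered pairs also gave 0. Every split but the real one mixes both lines in each group, so differences between the lines widen its spread and lower its count. The counts of 0 therefore do not measure what chance would give. For gene lists, 5 of the 10 splits gave at least the 10 of the real split, and the highest other was 13.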
